A study of Homo sapiens with 24 samples.

How the data were processed

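Polyadenylated RNA was sequenced from 24 libraries of 3 human breast cancer cell lines, HCC1395 (12 libraries), HCC38 (6) and HCC1937 (6). Each of the 8 groups, a line under a treatment, held 3 libraries with the replicate letters A, B and C. The authors' notes list fastp, HISAT2 2.0.5 and DESeq2 and the genome build hg38. The read counter, the annotation release and the strand setting are not given in the sources used here, and the kit text allows a directional or a non-directional library. The deposited file of each library holds raw counts per gene, 58735 entries keyed by gene symbol and in the same order in every file. The deposited normalised tables were not used here. In those of HCC38 and HCC1937 each value was the raw count times a constant per library. In that of HCC1395 the 12 columns carry the name of a line, HCC1935, that is in no label, and were not matched to samples.

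The files hold 57167 distinct symbols. Of these, 57142 are in GENCODE release 29, which gave gene types and positions, and 25 are not. Entries with symbols turned into dates by spreadsheet software number 27 (0.144 to 0.247% of a library's counts), and their symbols are among those 25. Entries that share a symbol with another number 1745 (0.03 to 0.04%). All of these stayed in the tests and none is named. Counts do not tell apart reads from near-identical gene copies. Of 134 named genes 35 overlap another tested gene in the annotation, 19 of them a protein-coding one. Without a known strand setting, pairs on opposite strands may share reads. Pairs on the same strand, such as SOX2 with SOX2-OT and NME1 with NME1-NME2, may share reads under any setting. Library totals ran from 33469927 to 51815656 counts. All libraries were kept.

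Genes were tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Each line had its own fit, and the 3 lines were fitted together for differences between lines. Genes passed filterByExpr (minimum count 10), libraries were scaled by TMM, dispersions were estimated with robust settings, and group means were compared by the two-sided quasi-likelihood test of edgeR. Benjamini-Hochberg adjusted p-values were called at 0.05 over the genes tested. The tests were 18074 genes in HCC1395, 17100 in HCC38, 17692 in HCC1937 and 20697 in the joint fit, with 8, 4, 4 and 16 residual degrees of freedom. The interaction in HCC1395 was the log2 change under both inhibitors less the sum of the changes under each. CPM values are scaled by TMM within the fit. Errors of log2 changes are standard errors of the fit, and those of CPM are SD of 3 libraries.

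Gene lists, 28 in all, were fixed before the data were examined, as were the comparisons, the tests and the rule for named genes. Lists with at least 4 tested members were tested by camera with a preset correlation of 0.01 between genes, two-sided, and adjusted over the lists tested in a comparison. An estimated correlation and fry were the alternatives. Each list count is also given adjusted over the list alone. The rule for named genes took, per comparison, the 8 largest and 8 smallest log2 changes among called protein-coding genes with a mean of at least 2 CPM and, for comparisons of 2 groups, no overlap between them. It added a panel of 16 genes with any p, and the 4 members of each list with the smallest p. The text names a part of these genes, and some are not reported here. Genes named because they stood out in all 3 lines were chosen after their values were seen.

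For genes called in all 3 lines, the number that independent lists would share was computed from the number called in each. The single-agent comparisons in HCC1395 share their DMSO libraries, so their overlap is set beside 20 simulations in which the DMSO and treated libraries were drawn from the same means. Correlations across genes have no p-value, since genes are not independent replicates. Replicate letters did not pair libraries across treatments. A blocked fit is given only as an alternative.

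The workflow was tested on simulated data made from the count levels and spread of these libraries, with 200 genes changed. These had a mean of at least 1 CPM, so recovery below that level was not measured. For EZH2i in HCC1395 it called 79.1% of genes changed 1.5-fold and 98.5% of those changed 2-fold, with 12 false calls among 16869 genes. For the interaction it called 68.7% and 86.6%, with 14 false calls among 16899 genes. In HCC38 it called 71.6% and 91%, with 12 among 16482, in HCC1937 82.1% and 98.5%, with 26 among 16823, and for the difference between HCC38 and HCC1395 44.8% and 76.1%, with 6 among 19695. In HCC1937 the 26 false calls stood beside 55, 66 and 65 recovered genes at 1.5-fold, 2-fold and 4-fold. False calls were a larger share of all calls than 0.05 in each of these but the difference between lines. Alternatives were RLE scaling (the size factors of DESeq2), no low-count filter, a stricter filter (1 CPM in 3 libraries), the Wald test of DESeq2 1.42.0, a replicate block, each library left out in turn, a threshold with at least 2-fold change, and fits of only the libraries compared.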

Results

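HCC1395, HCC38 and HCC1937 are established lines of triple-negative breast cancer, which lacks hormone receptors and HER2 amplification. Libraries came from cells given DMSO or both 5 uM tazemetostat, an inhibitor of the histone methyltransferase EZH2 (EZH2i), and 5 uM ipatasertib, an inhibitor of the AKT kinases (AKTi). HCC1395 was also given each inhibitor alone. The labels give a treatment timeline for another line and another assay, so the duration for these samples is not clear. Totals ran from 33469927 to 51815656 counts in HCC1395, from 33806811 to 41816594 in HCC38 and from 35506411 to 47370609 in HCC1937. Nothing says that replicates are separate cultures, so p-values measure only the spread between these samples, which may be technical.

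Groups parted on the first principal component in every line, with 40.6% of the variance in HCC1395, 66.0% in HCC38 and 79.4% in HCC1937. The mitochondrial share of counts moved with treatment in HCC1395, from 3.85% ± 0.08 (SD, n = 3) in DMSO to 4.75% ± 0.39 under EZH2i, 5.55% ± 0.19 under AKTi and 6.20% ± 0.09 under both. In HCC1937 it was 5.77% ± 0.84 in DMSO and 7.45% ± 0.96 under both. In HCC38 replicate C of EZH2i+AKTi stood apart, with a mitochondrial share of 7.77% against 4.76% and 5.19% in its fellow replicates. The share of ribosomal protein genes in HCC1395 was 5.84% ± 0.08 in DMSO, 6.37% ± 0.22 under EZH2i, 6.92% ± 0.25 under AKTi and 7.67% ± 0.98 under both, where replicate B had 8.75% against 7.43% and 6.83% in A and C. It was 5.26% ± 0.42 in DMSO and 4.51% ± 0.48 under both in HCC38, and 4.56% ± 0.26 and 5.33% ± 0.29 in HCC1937.

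**Figure D1:**
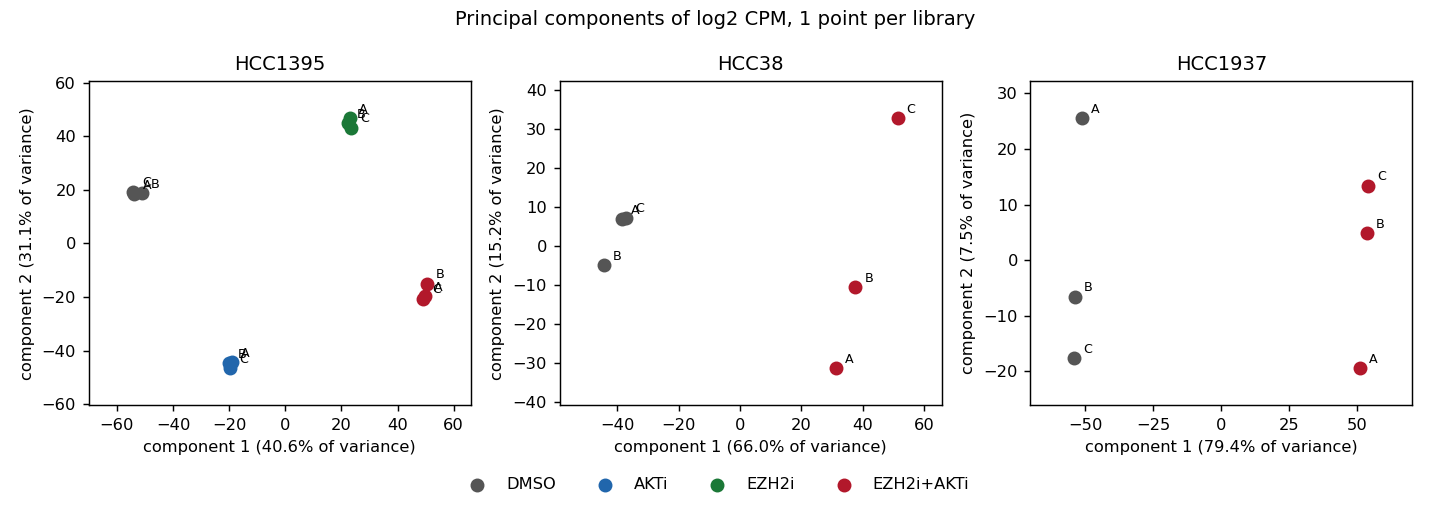
Principal components of log2 CPM per line, 1 point per library with its replicate letter, with the share of variance on each axis. In HCC38 replicate C of EZH2i+AKTi lies away from replicates A and B on component 2, which holds 15.2% of the variance.

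The first comparison asked which genes EZH2i alone changed in HCC1395. Genes almost silent in DMSO rose: SOX2, a stem cell transcription factor, from 0.33 to 9.29 CPM (log2 change 4.81 ± 0.31 SE, 3 libraries per group here and below), CCND2, which encodes cyclin D2, from 0.732 to 18.6 CPM (4.67 ± 0.13), the RNA-binding protein gene IGF2BP1 by 4.62 ± 0.19 and the protocadherin gene PCDH7 by 5.18 ± 0.32. FST, which encodes the activin antagonist follistatin, rose by 3.72 ± 0.15. BMF, which encodes a BH3-only promoter of cell death, rose from 11.1 to 46.9 CPM (2.08 ± 0.06, adjusted p = 2.4e-15). EZH2 itself was at 133 CPM in DMSO and 125 CPM under EZH2i (log2 change -0.08 ± 0.05, adjusted p = 0.202). The Wald test of DESeq2 called it, with adjusted p = 0.0403.

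Of 45 tested developmental regulators known as targets of Polycomb repression, 31 rose and 2 fell (median log2 change 0.63, camera adjusted p = 1.11e-08), as also adjusted over the list alone. DLX2 rose by 1.38 ± 0.11, FOXF1 by 1.67 ± 0.15 and HAND2 by 1.95 ± 0.18, all transcription factors of the embryo. Of 21 epithelial junction genes 13 rose and 0 fell (14 and 0 adjusted over the list alone, camera adjusted p = 2.44e-05), among them DSP, which encodes the desmosome protein desmoplakin, from 3.75 to 32.1 CPM (3.11 ± 0.19), and the tight junction gene TJP3 (1.40 ± 0.13). All 5 tested genes of CDK inhibitors rose (5 also adjusted over the list alone, camera adjusted p = 2.44e-05), including CDKN1A, which encodes p21 (1.07 ± 0.06), and CDKN1C, which encodes p57 (2.04 ± 0.19). Replication genes gave 11 lower and 2 higher of 35, also adjusted over the list alone (median -0.08, camera adjusted p = 0.0491, adjusted p = 0.0931 with an estimated correlation, 0.0516 with the replicate block). MKI67, a marker of cycling cells, was at 447 CPM in DMSO and 399 CPM under EZH2i (-0.16 ± 0.20, adjusted p = 0.596).

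Among interferon-stimulated genes 21 of 37 rose and 1 fell (22 and 2 adjusted over the list alone, camera adjusted p = 1.19e-05). That call was lost with adjusted p = 0.146 with an estimated correlation. The antiviral genes HERC5 (1.34 ± 0.08), MX1 (1.23 ± 0.10) and IFIT1 (1.09 ± 0.11) were among those that rose. Luminal mammary markers gave 10 higher and 1 lower of 21, also adjusted over the list alone (camera adjusted p = 0.00191, adjusted p = 0.0591 with an estimated correlation). The luminal progenitor gene ALDH1A3 rose by 1.19 ± 0.06, the epithelial transcription factor gene ELF3 by 1.96 ± 0.22 and the luminal keratin gene KRT18 by 0.72 ± 0.07. The basal keratin genes KRT5 (1.08 ± 0.10), KRT14 (0.44 ± 0.05) and KRT6B (1.42 ± 0.05) rose too, while basal and myoepithelial markers as a list gave 12 higher and 12 lower of 29, also adjusted over the list alone (camera adjusted p = 0.0686). GATA3, the luminal master regulator, was at 2.37 CPM in DMSO and 2.58 CPM under EZH2i (0.12 ± 0.18, adjusted p = 0.644).

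Inflammatory genes fell, with 10 of 24 genes of the NF-kB list lower and 1 higher (11 and 1 adjusted over the list alone, camera adjusted p = 0.0037). CXCL8, which encodes interleukin-8, fell by 1.45 ± 0.08 on the log2 scale, BIRC3, an inhibitor of apoptosis, by 0.91 ± 0.11 and the NF-kB subunit gene RELB by 0.47 ± 0.07. TNC, a matrix protein gene, fell from 1070 to 450 CPM, and the cytokine gene IL32 from 25 to 10.1 CPM. Ribosome biogenesis genes gave 16 lower and 0 higher of 28 (19 and 0 adjusted over the list alone, camera adjusted p = 2.44e-05), with NOLC1 at -0.44 ± 0.06 and DDX21 at -0.49 ± 0.07. FOXO and PI3K feedback genes gave 16 higher and 7 lower of 33 (19 and 9 adjusted over the list alone, camera adjusted p = 0.0478), a call lost with adjusted p = 0.269 with an estimated correlation, 0.0625 with RLE scaling and 0.0516 with the replicate block. FOXO1 rose by 1.02 ± 0.11 while IRS2, an insulin receptor adaptor gene, fell by 0.56 ± 0.08 and AKT1 by 0.18 ± 0.05. The quasi-likelihood test called 6087 of 18074 genes, 3402 higher and 2685 lower. Here lower genes were the more numerous with RLE scaling (3095 higher, 3511 lower), with DESeq2 (3018 and 3489) and without EZH2i replicate A (2730 and 2882). At 2-fold or more, 1337 were higher and 67 lower.

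AKTi alone was compared with DMSO in HCC1395 to see which genes follow the kinase. Genes of DNA replication fell: CDC6, which loads the replicative helicase, from 66.1 to 16.6 CPM (-1.99 ± 0.06), the helicase gene MCM6 from 160 to 51.0 CPM (-1.65 ± 0.05), MCM10 (-2.13 ± 0.07) and MYBL2, a transcription factor of cycling cells (-1.99 ± 0.05). Genes that FOXO transcription factors drive, or that feed back on PI3K, rose: PIK3IP1, a PI3K inhibitor gene, from 9.67 to 60.6 CPM (2.65 ± 0.07), FBXO32, a ubiquitin ligase gene, from 272 to 1010 CPM (1.89 ± 0.05), YPEL3 (2.76 ± 0.08), KLHL24 (2.23 ± 0.07) and IRS2 (1.70 ± 0.08). ITGB4, which encodes the laminin receptor integrin beta 4, rose from 30.9 to 218 CPM (2.82 ± 0.06, adjusted p = 2.6e-18). BMF rose from 11.1 to 63.4 CPM (2.51 ± 0.06), and BBC3, which encodes the death protein PUMA, by 1.69 ± 0.12.

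Of 35 tested genes of G1/S and DNA replication, 33 fell and 1 rose (camera adjusted p = 6.69e-85), and of 34 genes of G2/M and mitosis 28 fell and 0 rose (camera adjusted p = 7.07e-15). Adjusted over the list alone these were 33 and 1, and 32 and 0. CCNA2, which encodes cyclin A2, had a log2 change of -0.99 ± 0.05 and CDK1 of -0.81 ± 0.05. MKI67, at 447 CPM in DMSO and 312 CPM under AKTi, missed the threshold (-0.52 ± 0.20, adjusted p = 0.0628). It was called with RLE scaling (0.0487), the stricter filter (0.048), DESeq2 (0.0155) and without DMSO replicate C (0.0248). The p27 gene CDKN1B rose by 0.67 ± 0.04. The FOXO and PI3K feedback list gave 25 higher and 1 lower of 33, also adjusted over the list alone (camera adjusted p = 4.44e-31). ERK pathway output, genes induced by that kinase and feeding back on it, gave 19 higher and 0 lower of 21 (20 and 0 adjusted over the list alone, camera adjusted p = 2.49e-15), with SPRY2 at 1.58 ± 0.07, DUSP4 at 1.10 ± 0.05 and IER3 at 1.01 ± 0.06.

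Metabolic genes fell under AKTi. Cholesterol synthesis and uptake gave 20 lower and 1 higher of 24, also adjusted over the list alone (camera adjusted p = 8.57e-14), with ACAT2 at -1.17 ± 0.05, FDPS at -1.09 ± 0.05 and HMGCS1 at -0.83 ± 0.06. Fatty acid synthesis gave 12 lower and 2 higher of 17, also adjusted over the list alone (camera adjusted p = 0.00116). Glycolysis gave 13 lower and 3 higher of 21 (15 and 3 adjusted over the list alone, camera adjusted p = 6.18e-07), with PGK1 at -0.99 ± 0.05 and LDHA at -0.90 ± 0.05. Both have near-identical pseudogenes. Wound and hypoxia genes gave 13 lower and 4 higher of 19, also adjusted over the list alone (camera adjusted p = 6.87e-05), including the collagen hydroxylase gene P4HA1 (-1.08 ± 0.06). Ribosome biogenesis gave 21 lower and 2 higher of 28 (22 and 2 adjusted over the list alone, camera adjusted p = 1.46e-06), with the nucleolar gene NOP56 at -0.82 ± 0.05.

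Interferon-stimulated genes gave 24 higher and 2 lower of 37 under AKTi (25 and 2 adjusted over the list alone, camera adjusted p = 8.17e-08, adjusted p = 0.0648 with an estimated correlation). STAT2, a transducer of interferon signals, rose by 1.32 ± 0.07 and IFIT2 by 1.56 ± 0.10. Luminal markers gave 10 higher and 3 lower of 21, also adjusted over the list alone (camera adjusted p = 1.74e-04), with ALDH1A3 at 1.88 ± 0.06, KRT8 at 1.56 ± 0.08 and KRT18 at 0.76 ± 0.07. The annotated spans of KRT8 and KRT18 overlap on opposite strands, so without a known strand setting they may share reads. The junction gene JUP rose by 1.64 ± 0.06, the lipase gene PNPLA7 by 3.99 ± 0.13 and FOXO1 by 0.80 ± 0.11. KRT5 fell by 1.35 ± 0.12, CXCL8 by 1.15 ± 0.08, the retinoic acid carrier gene CRABP2 by 2.24 ± 0.14 and AKT1 by 0.31 ± 0.05. EZH2 fell from 133 to 75.0 CPM (-0.82 ± 0.05, adjusted p = 1.28e-11), while its paralog EZH1 rose from 6.55 to 13.3 CPM (1.02 ± 0.08). The test called 8979 of 18074 genes, 4892 higher and 4087 lower, with 890 and 474 at 2-fold or more. Lower genes were the more numerous with RLE scaling (4366 higher, 4558 lower), DESeq2 (4314 and 4517) and a fit of these 2 groups alone (4739 and 4864).

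EZH2i and AKTi each changed many genes in HCC1395, so their overlap was counted. The genes higher under both numbered 1341 and those lower under both 1181, where independent lists would share 920.8 and 607.1. The balance turned with RLE scaling (1119 higher, 1638 lower), DESeq2 (1064 and 1616), no filter (1099 and 1436) and without EZH2i replicate A (1042 and 1290). At 2-fold or more 203 were higher and 6 lower under both. Genes higher under EZH2i and lower under AKTi numbered 537, and 633 went the other way. BMF, ALDH1A3, KRT18, FOXO1 and CDKN1C were higher under each, and CXCL8 and AKT1 were lower under each. KRT5, CDKN1A and IRS2 moved in opposite directions. The log2 changes had a Pearson correlation of 0.212 and a covariance of 0.0936 across genes, and the same sign in 58.7% of genes. Unchanged groups simulated with shared DMSO libraries gave means of 0.513, 0.0427 and 66.8%. With no effect, the simulated correlation and share of signs arise from the spread between libraries alone. They therefore do not gauge how alike the responses to the inhibitors are. The covariance was above the simulated one by 0.0509. With nothing changed, at most 1 gene was called under both in the 20 simulations. Hardly any gene is called where nothing changes, so this gives no expected overlap for the real lists. Part of the excess over independent lists may come from the shared DMSO libraries, which are too few to split.

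The combination was compared with DMSO and with each agent in HCC1395. BMF reached 98.1 CPM (log2 change 3.14 ± 0.06 against DMSO), above either agent alone (1.06 ± 0.05 against EZH2i and 0.63 ± 0.05 against AKTi, adjusted p = 2.39e-12 and 1.99e-08). ITGB4 rose from 30.9 to 366 CPM (3.57 ± 0.06), ALDH1A3 from 42.3 to 248 CPM (2.55 ± 0.06), KRT18 by 1.45 ± 0.07 and KRT8 by 1.94 ± 0.08. The ubiquitin ligase gene FBXL7 (6.19 ± 0.30), the chromatin organiser gene SATB1 (5.62 ± 0.22) and FST (4.97 ± 0.14) rose from low levels. CLSPN, a replication checkpoint gene, fell by 2.45 ± 0.10, CDC6 by 2.21 ± 0.06, the chemokine gene CXCL12 by 2.20 ± 0.07 and MCM6 by 2.04 ± 0.05. EZH2 was at 72.6 CPM (-0.87 ± 0.05), and against AKTi alone it had a log2 change of -0.05 ± 0.05 (adjusted p = 0.506).

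Under the combination 33 of 37 interferon-stimulated genes rose and 1 fell (camera adjusted p = 1.81e-17), with IFIT1 from 9.48 to 52.1 CPM (2.46 ± 0.11), HERC5 at 1.95 ± 0.08 and the RNA sensor gene IFIH1 at 1.59 ± 0.07. Luminal markers gave 16 higher and 1 lower of 21 (17 and 1 adjusted over the list alone, camera adjusted p = 1.44e-06), and epithelial junction genes 15 higher and 0 lower of 21 (camera adjusted p = 6.41e-07), including TJP3 (2.12 ± 0.12). Developmental regulators gave 31 higher and 3 lower of 45 (camera adjusted p = 2.25e-06), with BMP4 at 1.48 ± 0.06. FOXO and PI3K feedback genes gave 28 higher and 2 lower of 33 (28 and 3 adjusted over the list alone, camera adjusted p = 2.35e-23), with TXNIP at 1.90 ± 0.05, PIK3IP1 at 2.87 ± 0.07 and FOXO1 at 1.33 ± 0.10. ERK pathway output gave 18 higher and 0 lower of 21 (camera adjusted p = 3.14e-14), with SPRY2 at 2.13 ± 0.07. Adjusted over the list alone the counts of interferon-stimulated, junction, developmental and ERK genes were the same.

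Lists of replication, metabolism, ribosome biogenesis and chaperone genes were lower under the combination. G1/S and DNA replication gave 33 lower and 0 higher of 35 (camera adjusted p = 7.51e-59), cholesterol synthesis and uptake 21 lower and 1 higher of 24 (camera adjusted p = 4.02e-08) with ACAT2 at -1.23 ± 0.05, glycolysis 14 lower and 4 higher of 21 (camera adjusted p = 6.41e-07) with PGK1 at -1.21 ± 0.05, wound and hypoxia genes 13 lower and 3 higher of 19 (camera adjusted p = 3.98e-05) with P4HA1 at -1.23 ± 0.06, ribosome biogenesis 22 lower and 2 higher of 28 (camera adjusted p = 5.48e-08) with NOP56 at -0.90 ± 0.05, and ER chaperones 13 lower and 3 higher of 19 (camera adjusted p = 1.92e-04) with CALR at -0.90 ± 0.05. All 6 counts were the same adjusted over the list alone. G2/M and mitosis gave 26 lower and 0 higher of 34 (28 and 1 adjusted over the list alone, camera adjusted p = 2.32e-05, adjusted p = 0.144 with an estimated correlation). MKI67 was at 315 CPM and missed the threshold (-0.51 ± 0.20, adjusted p = 0.0587). It was called with RLE scaling (0.0461), DESeq2 (0.016), without DMSO replicate C (0.0218) and without EZH2i+AKTi replicate C (0.0328). CDK inhibitors gave 3 higher and 1 lower of 5, also adjusted over the list alone (camera adjusted p = 0.0194, adjusted p = 0.123 with an estimated correlation). GATA3 rose from 2.37 to 3.93 CPM (0.72 ± 0.17), CDKN1A by 0.84 ± 0.06, CDKN1C by 3.16 ± 0.17, BBC3 by 1.74 ± 0.12, EZH1 by 0.92 ± 0.08, the autophagy gene GABARAPL1 by 1.21 ± 0.05 and the transcription factor gene CEBPD by 2.14 ± 0.08. The test called 10836 of 18074 genes, 5877 higher and 4959 lower (5322 and 5335 with DESeq2), with 2277 and 520 at 2-fold or more. Of these, 9177 were called in the same direction under a single agent and 1632 were called under neither.

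Against EZH2i alone the combination called 8855 genes, 4322 higher and 4533 lower (4696 and 4249 without EZH2i+AKTi replicate B, 730 and 521 at 2-fold or more). IRS2 rose by 2.06 ± 0.08, FBXO32 by 2.10 ± 0.05, the matrix gene CTGF by 2.42 ± 0.05, CEBPD by 1.96 ± 0.08, LTB, a cytokine gene, by 2.34 ± 0.21 and RELB by 0.67 ± 0.07. MCM6 fell by 1.83 ± 0.05, the desaturase genes FADS1 by 1.23 ± 0.05 and SCD by 0.92 ± 0.05, KRT5 by 1.53 ± 0.10 and CRABP2 by 3.07 ± 0.11. Against AKTi alone it called 6425 genes, 3067 higher and 3358 lower (3069 and 2586 without EZH2i+AKTi replicate B, 2724 and 2169 in a fit of these 2 groups alone, 1173 and 66 at 2-fold or more). CCND2 rose by 4.96 ± 0.14, IGF2BP1 by 5.80 ± 0.23, the junction genes JAM3 by 3.92 ± 0.14 and DSP by 3.22 ± 0.18, CD74, the invariant chain of antigen presentation, by 1.85 ± 0.12, KRT6B by 1.37 ± 0.05, KRT14 by 0.63 ± 0.05, CDKN1A by 1.03 ± 0.06 and the interferon-stimulated genes CMPK2 by 1.65 ± 0.14 and HERC5 by 1.12 ± 0.08. The growth factor gene GDF5 fell by 1.36 ± 0.07, TNC by 1.07 ± 0.08 and the lysosome membrane gene LAMP2 by 0.32 ± 0.04. Mitotic genes were higher against AKTi alone, with 17 higher and 0 lower of 34, also adjusted over the list alone (camera adjusted p = 0.00234, adjusted p = 0.219 with an estimated correlation), among them CDC20 at 0.36 ± 0.04.

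Lists placed the added effect of each inhibitor. Adding AKTi to EZH2i gave 33 lower and 1 higher of 35 replication genes (33 and 2 adjusted over the list alone, camera adjusted p = 1.38e-80), 25 higher and 4 lower of 33 FOXO and PI3K feedback genes (26 and 4 adjusted over the list alone, camera adjusted p = 9.08e-29), 20 higher and 0 lower of 21 ERK output genes (21 and 0 adjusted over the list alone, camera adjusted p = 5.4e-25), 31 higher and 0 lower of 37 interferon-stimulated genes (32 and 1 adjusted over the list alone, camera adjusted p = 5.42e-14) and 20 lower and 1 higher of 24 cholesterol genes (21 and 1 adjusted over the list alone, camera adjusted p = 2.6e-09). Adding EZH2i to AKTi gave 28 higher and 1 lower of 37 interferon-stimulated genes (30 and 1 adjusted over the list alone, camera adjusted p = 6.09e-14), 30 higher and 2 lower of 45 developmental regulators (31 and 2 adjusted over the list alone, camera adjusted p = 1.43e-09) and 16 higher and 0 lower of 21 junction genes, also adjusted over the list alone (camera adjusted p = 2.17e-08). These 3 calls were each lost with adjusted p = 0.0535 with an estimated correlation.

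**Figure D2:**
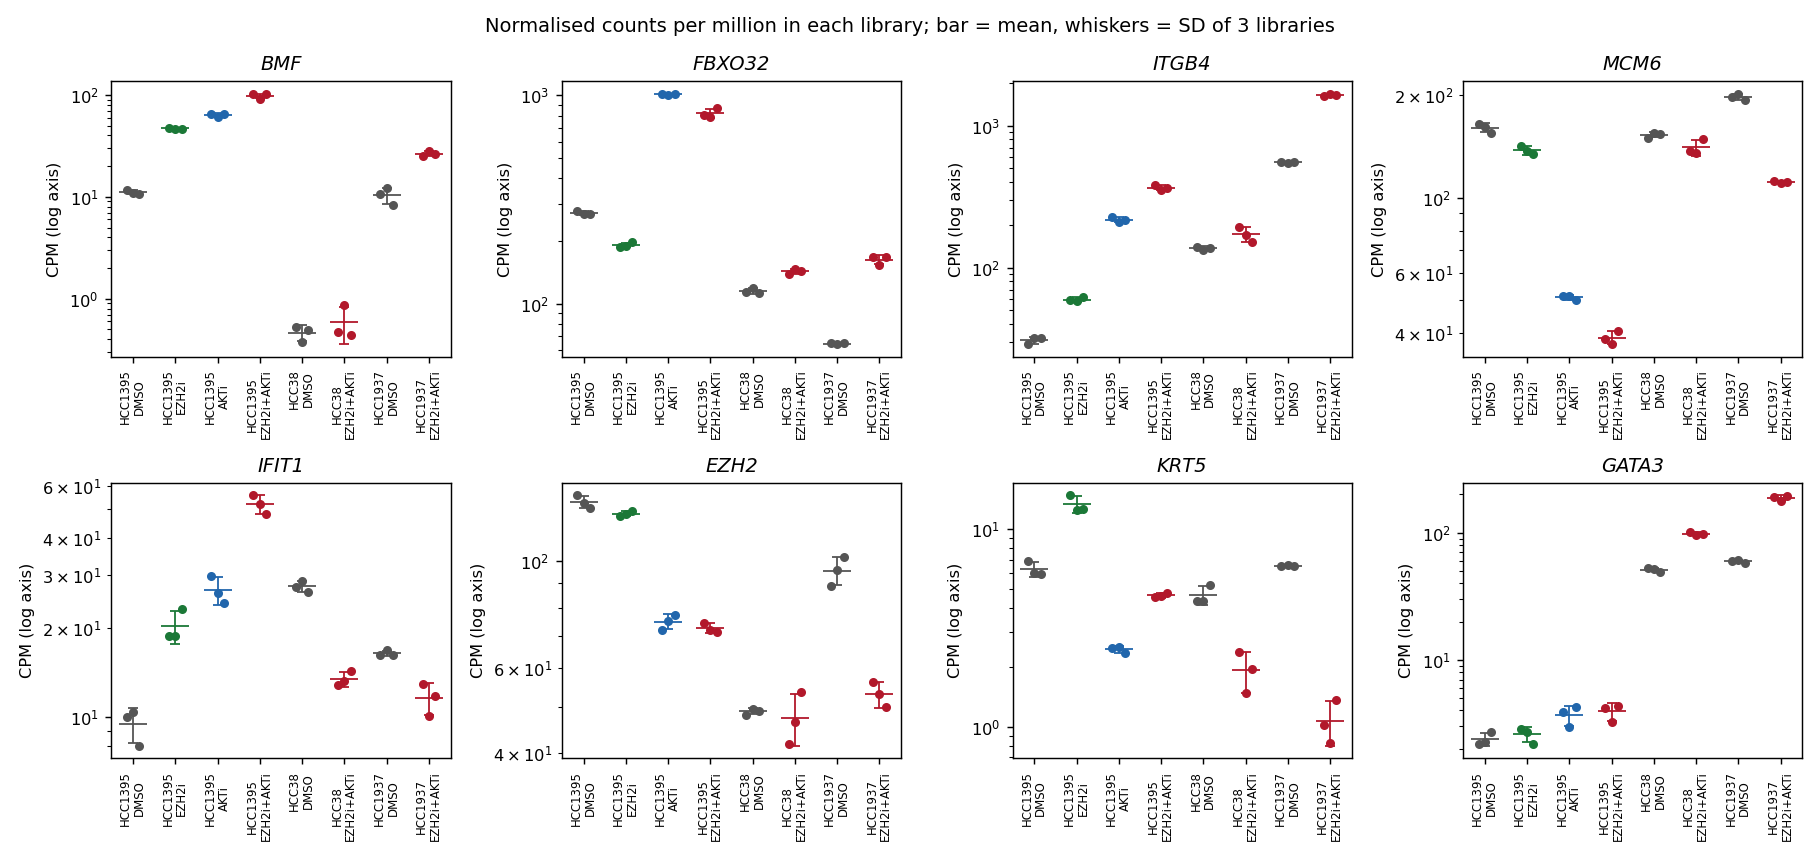
Normalised CPM (log axis) of 8 genes in each library, with the mean and SD of 3 libraries per group. In HCC1395 BMF goes from 11.1 CPM in DMSO to 98.1 CPM under EZH2i+AKTi.

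The interaction asked where the combination departs from the sum of the single-agent log2 changes. BMF departed downward by 1.45, with an interaction of -1.45 ± 0.08 (adjusted p = 2.26e-09), so its log2 rise, which took it to 98.1 CPM, was smaller than that sum. The interaction was tested on the log2 scale only. A departure there need not be a departure from the sum of the changes in CPM. CYP1A1, a detoxifying enzyme gene (-1.80 ± 0.17), PADI2, an arginine deiminase gene (-1.22 ± 0.10), the collagen gene COL1A1 (-0.74 ± 0.09), TXNIP (-0.61 ± 0.07) and ALDH1A3 (-0.52 ± 0.08) also had negative interactions. CXCL8 had a positive one (1.55 ± 0.11): from 41.8 CPM in DMSO it was at 15.3 CPM under EZH2i, 18.8 CPM under AKTi and 20.1 CPM under both. Positive interactions were also found for the metabolic enzyme gene NNMT (0.92 ± 0.13), CEBPD (0.74 ± 0.11), RELB (0.62 ± 0.10), BIRC3 (0.71 ± 0.15, adjusted p = 0.0145), FOSL1 (0.52 ± 0.08), TRIB3 (0.53 ± 0.08), PSAT1 (0.38 ± 0.07), SPRY2 (0.40 ± 0.09, adjusted p = 0.0279) and CDC20 (0.34 ± 0.06).

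Of 24 tested genes of the NF-kB list 6 had a positive and 0 a negative interaction (10 and 0 adjusted over the list alone, camera adjusted p = 2.22e-15). The ATF4 and amino acid response gave 6 and 0 of 28 (11 and 1 adjusted over the list alone, camera adjusted p = 1.59e-11) and ERK pathway output 5 and 0 of 21 (8 and 1 adjusted over the list alone, camera adjusted p = 2.65e-06). G2/M and mitosis gave 3 and 0 of 34 (7 and 0 adjusted over the list alone, camera adjusted p = 4.8e-11, adjusted p = 0.0715 with an estimated correlation). The test called 286 of 18074 genes, 95 positive and 191 negative, and 248 of the 286 were also called against DMSO. With RLE scaling 271 were called, 146 positive and 125 negative. The balance also turned with DESeq2 (280 and 197), no filter (219 and 203), without EZH2i replicate A (166 and 64) and without EZH2i+AKTi replicate B (485 and 145), so it is not settled. At 2-fold or more 4 were positive and 16 negative. The count moved with single libraries: it was 175 without DMSO replicate C, 155, 163 and 173 without AKTi replicates A, B and C, 127 and 148 without EZH2i replicates B and C, and 156, 630 and 1022 without EZH2i+AKTi replicates A, B and C. BIRC3 lost its call without AKTi replicate A (0.0551) or EZH2i replicate B (0.055). SPRY2 lost its call without DMSO replicate B (0.0761) or C (0.0822), AKTi replicate A (0.0506), B (0.0634) or C (0.0984), EZH2i replicate B (0.0631) or C (0.0675), or EZH2i+AKTi replicate A (0.0796).

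In HCC38 the combination was compared with DMSO to see whether another line responds alike. ESM1, an endothelial proteoglycan gene, rose by 5.08 ± 0.23, TFPI2, a protease inhibitor gene, by 3.55 ± 0.12 and the transcription cofactor gene LBH by 3.70 ± 0.21. WISP2, a matricellular gene, fell by 2.45 ± 0.20, TENT5A by 2.14 ± 0.17 and DDIT4, a brake on mTOR, by 2.07 ± 0.16. EZH2 was at 48.9 CPM in DMSO and 47.3 CPM under the combination (-0.05 ± 0.11, adjusted p = 0.771), and turned to 0.05 without EZH2i+AKTi replicate A.

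FOXO and PI3K feedback genes gave 18 higher and 1 lower of 31 in HCC38 (19 and 1 adjusted over the list alone, camera adjusted p = 9.1e-09), with PIK3IP1 at 2.54 ± 0.23, the insulin receptor gene INSR at 2.02 ± 0.13, KLHL24 at 1.91 ± 0.12 and FOXO1 at 1.82 ± 0.23. IRS2 did not pass (0.18 ± 0.10, adjusted p = 0.221). ERK pathway output gave 15 higher and 0 lower of 21, also adjusted over the list alone (camera adjusted p = 2.07e-14), with the phosphatase genes DUSP6 at 2.16 ± 0.11 and DUSP5 at 1.35 ± 0.09 and EGR1 at 1.91 ± 0.10. Mesenchymal genes gave 12 higher and 2 lower of 19, also adjusted over the list alone (camera adjusted p = 2.27e-05), with N-cadherin (CDH2) at 1.61 ± 0.10, SNAI2 at 1.45 ± 0.14 and fibronectin (FN1) at 1.11 ± 0.12. Developmental regulators gave 21 higher and 6 lower of 40 (24 and 6 adjusted over the list alone, camera adjusted p = 1.55e-04), with BMP2 at 1.72 ± 0.15 and LHX2 at 1.41 ± 0.14. Ribosome biogenesis gave 23 lower and 0 higher of 28, also adjusted over the list alone (camera adjusted p = 7.92e-09), with FBL at -0.71 ± 0.11 and LYAR at -0.74 ± 0.09.

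Glycolysis in HCC38 gave 12 lower and 0 higher of 20, also adjusted over the list alone (camera adjusted p = 5.53e-06, adjusted p = 0.226 with an estimated correlation), with GPI at -0.84 ± 0.09 and PGK1 at -0.64 ± 0.08. Wound and hypoxia genes gave 11 lower and 1 higher of 19 (12 and 1 adjusted over the list alone, camera adjusted p = 3.21e-05, adjusted p = 0.0538 with an estimated correlation), with P4HA1 at -1.01 ± 0.11. Replication genes gave 9 lower and 2 higher of 35, also adjusted over the list alone (camera adjusted p = 0.0162, adjusted p = 0.109 with an estimated correlation). TK1, a nucleotide salvage gene among them, was at -0.46 ± 0.11 (adjusted p = 0.0112), and lost its call without DMSO replicate B (0.0599) or EZH2i+AKTi replicate B (0.0814). MKI67 missed the threshold (0.27 ± 0.10, adjusted p = 0.0753) and was called higher with the stricter filter (0.0448) and without EZH2i+AKTi replicate A (0.0101) or C (0.00902). Interferon-stimulated genes gave 10 lower and 2 higher of 39, also adjusted over the list alone (camera adjusted p = 0.0285, adjusted p = 0.226 with an estimated correlation), with IFIT1 at -1.04 ± 0.10 and MX1 at -0.55 ± 0.10. Cholesterol genes gave 10 higher and 2 lower of 25 (12 and 2 adjusted over the list alone, camera adjusted p = 0.0359, adjusted p = 0.239 with an estimated correlation), with STARD4 at 1.61 ± 0.14.

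Luminal markers in HCC38 gave 10 higher and 5 lower of 22 (12 and 6 adjusted over the list alone, camera adjusted p = 0.0205, adjusted p = 0.226 with an estimated correlation). GATA3 (0.95 ± 0.09) and FOXA1 (2.19 ± 0.15), both luminal regulators, rose and KRT5 fell by 1.26 ± 0.19. KRT18 rose by 0.40 ± 0.11 (adjusted p = 0.0199), a call lost without DMSO replicate A (0.0906) or C (0.0956) or EZH2i+AKTi replicate B (0.0785). CDKN1A rose by 1.79 ± 0.12, CDKN1C by 1.99 ± 0.16, EZH1 by 0.60 ± 0.13, the tight junction gene CLDN1 by 2.60 ± 0.12 and the BH3-only gene HRK by 1.84 ± 0.17. BMF was below 1 CPM in both groups (0.464 and 0.593 CPM, adjusted p = 0.47), and AKT1 did not pass (-0.12 ± 0.10, adjusted p = 0.406). The test called 5362 of 17100 genes, 2874 higher and 2488 lower, with 1179 and 196 at 2-fold or more. The median standard error of the log2 changes was 0.14 here, against 0.1 in HCC1395 and 0.0984 in HCC1937 under the combination. Fewer calls in HCC38 therefore need not by themselves mean a smaller response. The count was 3520 without DMSO replicate A, 3114 without DMSO replicate B and 3300 (2240 higher, 1060 lower) without EZH2i+AKTi replicate B. Without EZH2i+AKTi replicate C, the library with the highest mitochondrial share in this line, it was 6697. It was 6715 without EZH2i+AKTi replicate A, the library with the lowest.

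In HCC1937 the combination raised CLEC2B, a lectin gene, by 6.91 ± 0.22, the matrix gene CTGF from 5.20 to 169 CPM (5.02 ± 0.12) and ANKRD1, another target of the YAP coactivator, by 4.97 ± 0.09. KRT13 fell from 577 to 51.4 CPM (-3.49 ± 0.20), STC1, a hypoxia-induced hormone gene, by 2.91 ± 0.10, KRT5 by 2.59 ± 0.17 and KRT14 by 1.17 ± 0.13, while GATA3 rose from 59.6 to 188 CPM (1.66 ± 0.06, adjusted p = 8.03e-12). Luminal markers as a list gave 8 higher and 8 lower of 24, also adjusted over the list alone (camera adjusted p = 0.797, median -0.01, mean 0.08, upward test, so median and mean differ in sign). Of genes that promote cell death, HRK rose by 2.72 ± 0.08, BBC3 by 2.20 ± 0.15 and BMF by 1.36 ± 0.11. The BCL2 family and death receptor list gave 7 higher and 7 lower of 25, also adjusted over the list alone (camera adjusted p = 0.342, median -0.02, mean 0.21, upward test, so median and mean differ in sign). EZH2 fell from 95.6 to 53 CPM (-0.85 ± 0.07), SUZ12, another PRC2 subunit gene, by 0.75 ± 0.06, and EZH1 rose by 0.93 ± 0.08.

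Replication genes in HCC1937 gave 34 lower and 1 higher of 35 (camera adjusted p = 2.39e-26), with RRM2 at -1.46 ± 0.06, CDC6 at -1.51 ± 0.06 and CLSPN at -1.96 ± 0.09, and MKI67 fell by 0.75 ± 0.06. Mitotic genes gave 27 lower and 0 higher of 34 (camera adjusted p = 2.23e-05, adjusted p = 0.386 with an estimated correlation). FOXO and PI3K feedback genes gave 27 higher and 3 lower of 32 (camera adjusted p = 1.02e-22), with PIK3IP1 at 3.98 ± 0.10, KLHL24 at 2.64 ± 0.08 and IRS2 at 1.41 ± 0.07. Glycolysis gave 18 lower and 1 higher of 20 (camera adjusted p = 2.71e-18, adjusted p = 0.0727 with an estimated correlation), with LDHA at -1.86 ± 0.05, GPI at -1.92 ± 0.06 and PGK1 at -1.65 ± 0.06. Wound and hypoxia genes gave 15 lower and 2 higher of 19 (camera adjusted p = 4.38e-15), with P4HA1 at -2.07 ± 0.06 and BNIP3 at -1.88 ± 0.06. All 5 counts were the same adjusted over the list alone.

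ERK pathway output in HCC1937 gave 17 higher and 0 lower of 21 (18 and 0 adjusted over the list alone, camera adjusted p = 3.71e-11, adjusted p = 0.159 with an estimated correlation), with DUSP6 at 2.84 ± 0.09 and ETV5 at 1.30 ± 0.07. The ATF4 and amino acid response gave 16 higher and 5 lower of 28, also adjusted over the list alone (camera adjusted p = 1.6e-05, adjusted p = 0.159 with an estimated correlation), with GDF15 at 2.52 ± 0.07 and the serine synthesis gene PHGDH at 1.55 ± 0.07. Antigen presentation gave 13 higher and 2 lower of 23, also adjusted over the list alone (camera adjusted p = 5.5e-04, adjusted p = 0.356 with an estimated correlation), with CD74 at 2.09 ± 0.09 and HLA-B at 1.11 ± 0.07. Ribosome biogenesis gave 23 lower and 0 higher of 28, also adjusted over the list alone (camera adjusted p = 4.66e-06, adjusted p = 0.356 with an estimated correlation), with BOP1 at -0.94 ± 0.06. Developmental regulators gave 20 higher and 4 lower of 41, also adjusted over the list alone, with camera adjusted p = 0.147, and FOXF1 rose by 2.10 ± 0.11. Interferon-stimulated genes gave 9 higher and 18 lower of 39, also adjusted over the list alone, with camera adjusted p = 0.0671 and OAS3 at -1.08 ± 0.07. CDK inhibitors gave 5 higher and 1 lower of 7 (5 and 2 adjusted over the list alone, camera adjusted p = 0.00634, adjusted p = 0.386 with an estimated correlation). CDKN2B rose by 1.97 ± 0.07, CDKN1C by 1.72 ± 0.10, GABARAPL1 by 2.51 ± 0.07, CLDN1 by 1.68 ± 0.06, ITGB4 by 1.58 ± 0.05 and the kinase gene PIM1 by 1.76 ± 0.06, and E-cadherin (CDH1) fell by 1.20 ± 0.06. The test called 10491 of 17692 genes, 5399 higher and 5092 lower, with 2046 and 556 at 2-fold or more. Lower genes were the more numerous with RLE scaling (5234 higher, 5297 lower), DESeq2 (4890 and 5102) and without EZH2i+AKTi replicates A (5238 and 5331) or C (4798 and 4934).

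**Figure D3:**
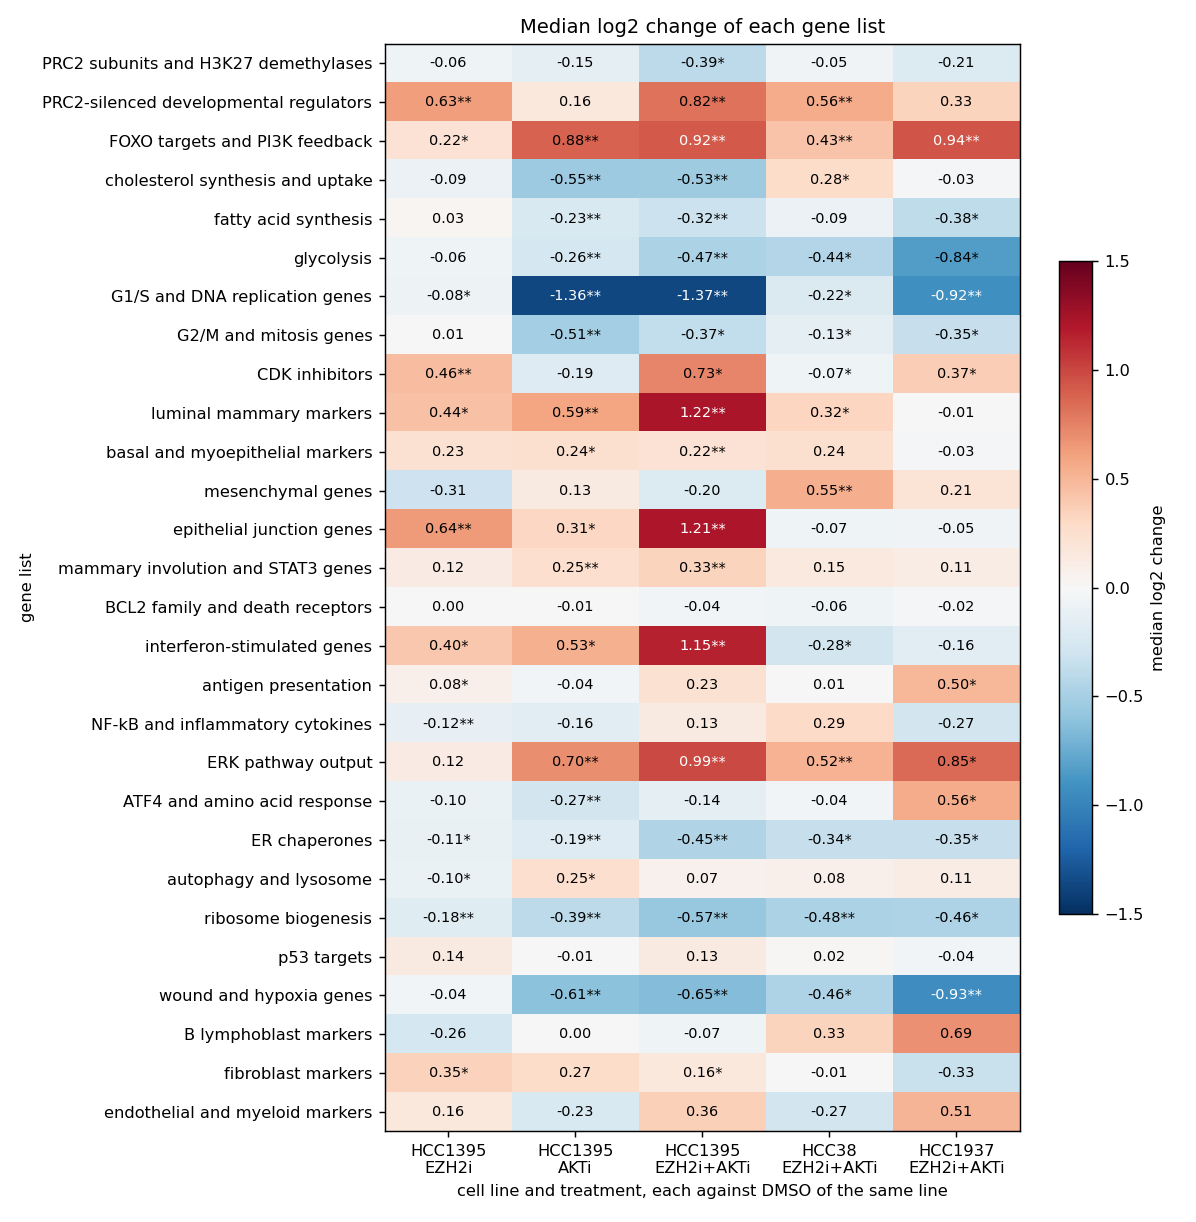
Median log2 change of each of 28 gene lists in 5 comparisons with DMSO (color scale and printed value). A star marks lists called by camera, and a double star those called also with an estimated correlation. G1/S and DNA replication genes stand at -1.37 in HCC1395, -0.22 in HCC38 and -0.92 in HCC1937 under EZH2i+AKTi.

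Genes that moved the same way in all 3 lines were counted next. LBH rose by 3.77 ± 0.08 in HCC1395, 3.70 ± 0.21 in HCC38 and 4.81 ± 0.07 in HCC1937, CLEC2B by 4.32 ± 0.17, 4.53 ± 0.69 and 6.91 ± 0.22, CTGF by 2.33 ± 0.05, 2.56 ± 0.11 and 5.02 ± 0.12, ESM1 by 4.02 ± 0.62, 5.08 ± 0.23 and 4.13 ± 0.18, and KLHL24 by 2.16 ± 0.07, 1.91 ± 0.12 and 2.64 ± 0.08. NME1, a nucleotide kinase gene, had log2 changes of -1.62 ± 0.08, -0.86 ± 0.12 and -1.33 ± 0.08, the mitochondrial chaperone gene HSPD1 of -1.13 ± 0.05, -0.79 ± 0.09 and -1.18 ± 0.06, and the mitochondrial import gene TOMM40 of -1.14 ± 0.05, -0.95 ± 0.18 and -0.81 ± 0.08. These genes were chosen after their values were seen, from large shared changes. PIK3IP1 and CDKN1C rose and PGK1 and P4HA1 fell in every line. Of 14980 genes tested in all 3 lines, 1168 were higher and 1099 lower in each, where independent lists would share 222.6 and 239.8. With DESeq2 these were 1107 and 1157, without HCC1395 EZH2i+AKTi replicate B 1139 and 1141, and at 2-fold or more 237 and 9. Their sum, 2267, was 1503 without HCC38 DMSO replicate B and 1471 (962 higher, 509 lower) without HCC38 EZH2i+AKTi replicate B.

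Across genes, the log2 changes of HCC1395 and HCC1937 had a Pearson correlation of 0.564 (Spearman 0.613), those of HCC1395 and HCC38 0.446 (0.387) and those of HCC38 and HCC1937 0.486 (0.408). Without the low-count filter, which adds genes with few counts, these were 0.24 (0.323), 0.155 (0.2) and 0.198 (0.243). Genes are not independent replicates, so no p-value is given for these 3 pairs. The genes called under a single agent in HCC1395 were then followed in the other lines. The sets of the agents overlap, with 1341 genes higher and 1181 lower under each. HCC38 and HCC1937 were given only the combination, so these sets do not tell the effects of the agents apart there. Genes raised by EZH2i alone were higher as a set in HCC38 (camera adjusted p = 2.13e-14) and HCC1937 (1.15e-11), and genes raised by AKTi alone likewise (8.77e-08 and 6.21e-14). Genes lowered by AKTi alone were lower in HCC38 (2.12e-10) and HCC1937 (3.8e-24), and so were genes lowered by EZH2i alone (0.0023 and 2.85e-10). With an estimated correlation the call of genes lowered by EZH2i was lost in HCC38 (adjusted p = 0.0804 with an estimated correlation).

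**Figure D4:**
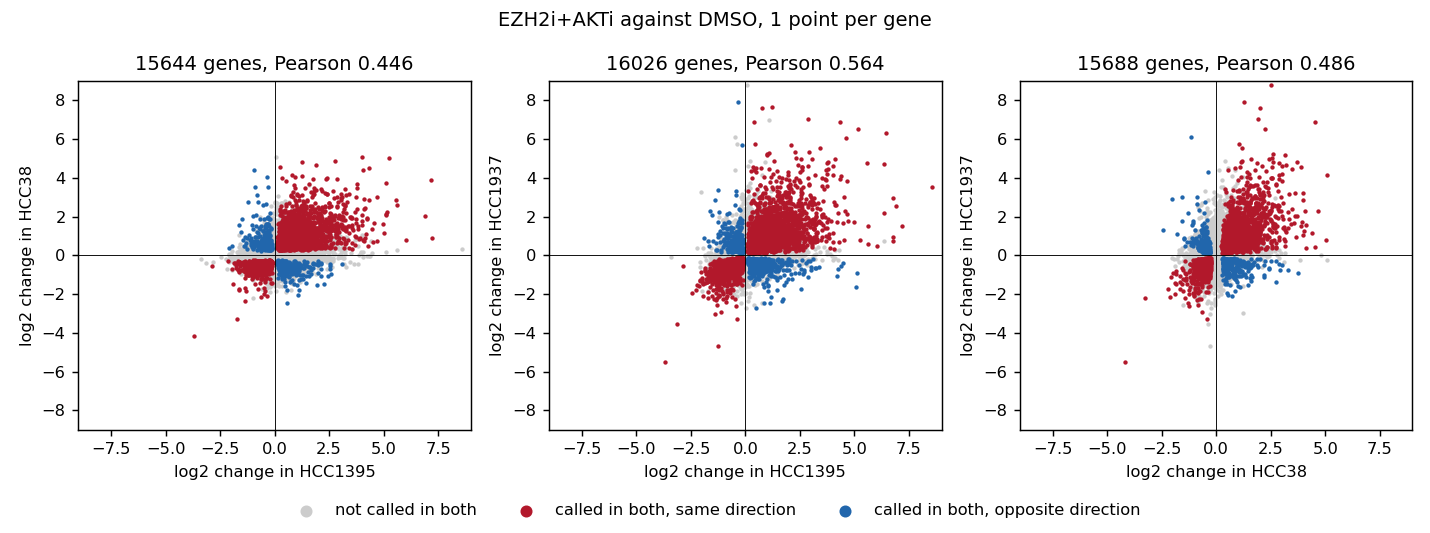
Log2 change under EZH2i+AKTi in each pair of lines, 1 point per gene tested in both, colored where called in both lines. The Pearson correlation across genes is 0.446 for HCC1395 and HCC38, 0.564 for HCC1395 and HCC1937 and 0.486 for HCC38 and HCC1937 among genes that passed the low-count filter.

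Differences between lines in the response to the combination were tested directly. The joint fit shared its spread between the 3 lines, with a common coefficient of variation between libraries of 0.0859. In their own fits it was 0.122 for HCC38, 0.0653 for HCC1395 and 0.0748 for HCC1937. Errors and p-values of differences with HCC38 may therefore be too small, and their counts of genes too large. Replication genes fell less in HCC38 than in HCC1395, with 32 higher and 1 lower of 35 in the difference (33 and 1 adjusted over the list alone, camera adjusted p = 1.7e-60), MCM6 at 1.94 ± 0.08 and CDC6 at 2.07 ± 0.09. Interferon-stimulated genes responded lower in HCC38, with 30 lower and 0 higher of 39 (32 and 0 adjusted over the list alone, camera adjusted p = 2.09e-32), IFIT1 at -3.48 ± 0.15 and MX1 at -3.07 ± 0.14. Epithelial junction genes gave 16 lower and 1 higher of 25 (18 and 2 adjusted over the list alone, camera adjusted p = 5.93e-15), with JUP at -1.81 ± 0.10, and cholesterol genes 18 higher and 0 lower of 25 (19 and 0 adjusted over the list alone, camera adjusted p = 6.66e-17), with ACAT2 at 1.31 ± 0.09. FOXO and PI3K feedback genes gave 14 lower and 3 higher of 33, also adjusted over the list alone (camera adjusted p = 4.6e-04, adjusted p = 0.0748 with an estimated correlation). CDH2 (1.93 ± 0.10) and EZH2 (0.84 ± 0.10) were higher in the difference, and ITGB4 (-3.21 ± 0.10), ALDH1A3 (-2.96 ± 0.09) and BMF (-2.74 ± 0.33) lower. BMF is near the limit of detection in HCC38. The test called 6833 of 20697 genes, 3595 higher and 3238 lower, and at 2-fold or more 866 and 1296.

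Against HCC1937, the response of HCC38 was higher for replication genes, with 27 higher and 1 lower of 35 (29 and 1 adjusted over the list alone, camera adjusted p = 2.66e-25), RRM2 at 1.63 ± 0.11 and CDC6 at 1.37 ± 0.09. Glycolysis gave 15 higher and 2 lower of 21 (16 and 2 adjusted over the list alone, camera adjusted p = 2.11e-08, adjusted p = 0.0531 with an estimated correlation), with GPI at 1.11 ± 0.08. The ATF4 list gave 17 lower and 2 higher of 28 (19 and 2 adjusted over the list alone, camera adjusted p = 9.22e-11), with PHGDH at -2.17 ± 0.11, and antigen presentation 14 lower and 1 higher of 24 (15 and 1 adjusted over the list alone, camera adjusted p = 2.08e-05, adjusted p = 0.0531 with an estimated correlation). FOXO and PI3K feedback genes gave 16 lower and 5 higher of 33 (16 and 7 adjusted over the list alone, camera adjusted p = 5.63e-06). FOXA1 (2.72 ± 0.16), STC1 (2.27 ± 0.15), CDKN1A (1.47 ± 0.12) and EZH2 (0.83 ± 0.10) were higher in the difference. The test called 6628 genes, 3661 higher and 2967 lower, and at 2-fold or more 824 and 1037.

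HCC1937 against HCC1395 gave 4825 genes, 2332 higher and 2493 lower (2433 and 2404 with RLE scaling, 2615 and 2551 with DESeq2, 2801 and 2213 with the stricter filter, 2830 and 2344 in a fit of these groups alone, 812 and 968 at 2-fold or more). Interferon-stimulated genes responded lower in HCC1937, with 30 lower and 0 higher of 39 (33 and 0 adjusted over the list alone, camera adjusted p = 7.59e-44), IFIT1 at -2.96 ± 0.15 and MX1 at -2.37 ± 0.14. Epithelial junction genes gave 19 lower and 2 higher of 25 (19 and 4 adjusted over the list alone, camera adjusted p = 1.61e-22), with DSP at -4.02 ± 0.20. The ATF4 list gave 16 higher and 2 lower of 28 (18 and 2 adjusted over the list alone, camera adjusted p = 9.28e-12), with PHGDH at 1.40 ± 0.11, and replication genes 23 higher and 2 lower of 35 (25 and 2 adjusted over the list alone, camera adjusted p = 2.92e-12), with MCM6 at 1.20 ± 0.08. GATA3 (0.94 ± 0.16) was higher in the difference, and ITGB4 (-1.99 ± 0.09), BMF (-1.79 ± 0.15) and GPI (-1.23 ± 0.08) were lower. EZH2 did not differ by more than its error (0.01 ± 0.10, adjusted p = 0.978).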

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

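The tests chosen after the result was seen are the counts of library splits and the test of a missing drug effect in HCC38. The list medians of interferon-stimulated genes were also read after it was seen. The other tests below were set before their values were seen.

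The first pattern is the smaller fall of replication genes in HCC38 than in the other lines. It did not hang on HCC38 EZH2i+AKTi replicate C, since without it the median difference was 0.74 against HCC1937 (0.76 with it) and 1.26 against HCC1395. A lack of any drug effect is argued against, since the mean log2 CPM of 31 FOXO and PI3K feedback genes was higher by 0.77 ± 0.02 (standard error, 3 libraries per group) under EZH2i+AKTi. This does not show which drug acted. A weaker effect of AKTi in HCC38 stays open, since the response of this list was lower there, with a median difference of -0.29 against HCC1395 and -0.51 against HCC1937 (adjusted p = 0.0748 and 0.0342 with an estimated correlation). A line-specific link between AKT and the cell cycle is an untested hypothesis, which AKTi alone in HCC38, with AKT activity and growth measured, would decide.

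The second pattern is the rise of interferon-stimulated genes in HCC1395 and not in HCC38 or HCC1937. A higher level before treatment could leave less room to rise: 37.8% of 37 list members in HCC38 DMSO (14 genes), and 29.7% in HCC1937 DMSO (11 genes), were at or above their level in treated HCC1395. These shares lie between the bounds set in advance, so they do not decide. The list median was 21.7 CPM in HCC38 DMSO and 16.2 CPM in HCC1937 DMSO, and 17.9 and 14.7 CPM under EZH2i+AKTi. In HCC1395 it was 11.4 CPM in DMSO, 15.1 CPM under EZH2i, 20.4 CPM under AKTi and 28.4 CPM under both. Levels near those of the other lines thus left room to rise in HCC1395. For the list as a set these medians argue only against a ceiling at a level common to the lines. They cannot tell whether HCC38 or HCC1937 has a lower ceiling of its own, so less room to rise stays open there. It also stays open for the 14 and 11 genes. A single HCC1395 library does not account for the rise, since at least 31 members were called higher whichever of the 6 libraries was left out.

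Splits of the libraries were counted for each number of genes. In the 7 comparisons of 2 groups of 3 libraries there are only 10 splits, too few for a share under 0.05. The real groups gave 6087, 8979, 10836, 8855, 6425, 5362 and 10491 genes, and the highest other split gave 0 in each. For the interaction (286 genes), the genes shared by EZH2i and AKTi (2522) and those shared by all 3 lines (2267), 1 of 100 splits, the real one, was as large and the highest other gave 0. For HCC38 against HCC1395 2 of 100 splits were as large (highest other 6918, real 6833) and for HCC38 against HCC1937 4 of 100 (highest other 7116, real 6628). For these 5 counts chance can be excluded only as a random placement of libraries. The other splits mix drug effects into the groups, so they do not test whether the sharing, the departure from the sum or the difference between lines is beyond chance. For HCC1937 against HCC1395 12 of 100 were as large (highest other 6846, real 4825), so this share does not exclude chance. It does not speak for chance either, since the other splits as large carry the drug effect of the line kept whole. All of the other splits as large (1, 3 and 11) kept the treatment groups of a line whole and mixed the other line, which points to the structure of the samples. Splits that mixed both lines gave at most 2, 1 and 1 genes.

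Responses that differed by a test of the difference were these. In the HCC1395 interaction, 286 genes differed, among them CXCL8 (1.55), RELB (0.62), CEBPD (0.74), NNMT (0.92), TRIB3 (0.53), PSAT1 (0.38), FOSL1 (0.52), BIRC3 (0.71), SPRY2 (0.40), CDC20 (0.34), BMF (-1.45), CYP1A1 (-1.80), PADI2 (-1.22), TXNIP (-0.61), COL1A1 (-0.74) and ALDH1A3 (-0.52). The list medians were 0.32 for NF-kB, 0.24 for ATF4, 0.09 for ERK output and 0.16 for G2/M genes, the last lost with adjusted p = 0.0715 with an estimated correlation.

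Between HCC38 and HCC1395, 6833 genes differed in response, among them MCM6 (1.94), CDC6 (2.07), CDH2 (1.93), ACAT2 (1.31), EZH2 (0.84), IFIT1 (-3.48), MX1 (-3.07), BMF (-2.74), ALDH1A3 (-2.96), ITGB4 (-3.21) and JUP (-1.81), with list medians of 1.28 for replication, -1.31 for interferon-stimulated, 0.78 for cholesterol, -1.02 for junction and -0.29 for FOXO and PI3K feedback genes, the last lost with adjusted p = 0.0748 with an estimated correlation. Between HCC38 and HCC1937, 6628 genes differed, among them CDC6 (1.37), RRM2 (1.63), GPI (1.11), STC1 (2.27), FOXA1 (2.72), EZH2 (0.83), CDKN1A (1.47) and PHGDH (-2.17), with list medians of 0.76 for replication, 0.53 for glycolysis, -0.57 for ATF4, -0.66 for antigen presentation and -0.51 for FOXO and PI3K feedback. Of these, glycolysis and antigen presentation were each lost with adjusted p = 0.0531 with an estimated correlation. Between HCC1937 and HCC1395, 4825 genes differed, among them MCM6 (1.20), PHGDH (1.40), GATA3 (0.94), IFIT1 (-2.96), MX1 (-2.37), BMF (-1.79), ITGB4 (-1.99), DSP (-4.02) and GPI (-1.23), with list medians of -1.17 for interferon-stimulated, -1.32 for junction, 0.42 for replication and 0.63 for ATF4 genes.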

How the results depend on the processing

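No test here was chosen after its result was seen, but 17 of the named gene values were of genes chosen for large shared changes. For the results that changed, the cause was not tested unless stated. The others, but for the panel, were picked for large called changes or small p in these same data. The counts of values kept therefore do not measure how well gene calls hold in general. Of 285 named gene values, RLE scaling kept the direction and call of 283, the DESeq2 Wald test 282, and no filter and the replicate block all 285. The stricter filter kept 280 of 282. The rest of these became calls. EZH2 under EZH2i was such a gene (adjusted p = 0.0403 with DESeq2). Leaving out 1 library kept 1955 of 1980 values, with 15 calls lost, 5 gained and 5 signs turned. Those signs were of EZH2, which was not called: -0.11 to 0.05 in HCC38 and -0.04 to 0.05 for HCC1937 less HCC1395, with 0.05, -0.02, 0, -0.04 and -0.03 where it turned. Asking for at least 2-fold leaves fewer genes by construction: 1404 (EZH2i), 1364 (AKTi), 2797 (both), 1251 (both against EZH2i), 1239 (both against AKTi), 20 (interaction), 1375 (HCC38), 2602 (HCC1937), 2162 (HCC38 less HCC1395), 1861 (HCC38 less HCC1937), 1780 (HCC1937 less HCC1395), 246 (all 3 lines) and 209 (shared by EZH2i and AKTi). The interaction gave 477 genes with the DESeq2 Wald test and 247 with the replicate block, beside 286. With libraries left out it ranged from 127 to 1022, HCC38 from 3114 to 6715 and the genes shared by all 3 lines from 1471 to 2883. Interaction counts were 175 without DMSO replicate C, 155, 163 and 173 without AKTi replicates A, B and C, 127 and 148 without EZH2i replicates B and C, and 156, 630 and 1022 without EZH2i+AKTi replicates A, B and C. HCC38 gave 3520 and 3114 without DMSO replicates A and B and 3300 without EZH2i+AKTi replicate B, and all 3 lines gave 1503 and 1471 without HCC38 DMSO replicate B and EZH2i+AKTi replicate B. Without a low-count filter, which adds genes with few counts, Pearson and Spearman correlations were 0.155 and 0.2 (HCC1395 and HCC38), 0.24 and 0.323 (HCC1395 and HCC1937) and 0.198 and 0.243 (HCC38 and HCC1937). The stricter filter gave 0.6 and 0.649 for HCC1395 and HCC1937, and libraries left out gave 0.541 to 0.559 and 0.589 to 0.614. Of 143 list calls, 80 remained with an estimated correlation, and fry called 235 lists in all and kept 141 of the 143. Unlike camera, fry asks whether list members change at all, not whether they change more than other genes. Where many genes are called, the calls it kept therefore say little about how well list calls hold. RLE scaling kept 139 and the replicate block 136. Genes lowered by EZH2i in HCC1395 lost their call in HCC38 with an estimated correlation (0.0804). With 3 libraries per group and 33469927 counts or more, changes of 2-fold were called in simulation in 98.5% of cases for EZH2i, and in 76.1% for a difference between lines. These cases were genes with a mean of at least 1 CPM.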

Other observations

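The values below carry no test of an explanation, and none of their tests was chosen after the result was seen. Lists with at least 4 tested members were tested in each comparison, and the text gives a part of the calls. Some of the others follow. The mammary involution and STAT3 list gave 18 higher and 4 lower of 32 under AKTi in HCC1395 (median 0.25, camera adjusted p = 0.002) and 20 higher and 7 lower under both (median 0.33, camera adjusted p = 2.78e-04), the same adjusted over the list alone. In HCC38 it gave 13 higher and 7 lower (13 and 8 adjusted over the list alone, median 0.15, camera adjusted p = 0.152), and in HCC1937 13 higher and 10 lower of 32, also adjusted over the list alone (median 0.11, camera adjusted p = 0.0637). Basal and myoepithelial markers gave 16 higher and 5 lower of 29 under both in HCC1395 (18 and 5 adjusted over the list alone, median 0.22, camera adjusted p = 1.01e-04), and 12 higher and 14 lower of 30 in HCC1937 (13 and 14 adjusted over the list alone, median -0.03, camera adjusted p = 0.38). PRC2 subunits and H3K27 demethylases gave 0 higher and 3 lower of 13 under EZH2i (0 and 0 adjusted over the list alone, median -0.06, camera adjusted p = 0.282), and 4 higher and 7 lower under both in HCC1395, also adjusted over the list alone (median -0.39, camera adjusted p = 0.0488, adjusted p = 0.144 with an estimated correlation, 0.0533 with the replicate block).

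Autophagy and lysosome genes gave 3 higher and 12 lower of 31 under EZH2i in HCC1395 (4 and 12 adjusted over the list alone, median -0.10, camera adjusted p = 0.0467, adjusted p = 0.238 with an estimated correlation, 0.0516 with the replicate block), and 19 higher and 5 lower under AKTi (20 and 5 adjusted over the list alone, median 0.25, camera adjusted p = 0.00152, adjusted p = 0.0667 with an estimated correlation). The BCL2 family and death receptors gave 8 higher and 5 lower of 24 under both in HCC1395, also adjusted over the list alone (camera adjusted p = 0.142, median -0.04, mean 0.39, so median and mean differ in sign). The p53 targets gave 9 higher and 5 lower of 22, also adjusted over the list alone (median 0.13, camera adjusted p = 0.585). In HCC38 the CDK inhibitor list gave 2 higher and 1 lower of 5, also adjusted over the list alone, with a median of -0.07, a mean of 0.60 and an upward test (camera adjusted p = 0.0345, adjusted p = 0.353 with an estimated correlation).

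Markers of other cell types were tested for a change under treatment, which cannot show a mixture present alike in both groups. B lymphoblast markers gave 1 higher and 2 lower of 7 under both in HCC1395 (median -0.07, mean 0.09, downward test, camera adjusted p = 0.411), 3 higher and 1 lower of 8 in HCC38 (median 0.33, 0.533) and 4 higher and 1 lower of 7 in HCC1937 (median 0.69, 0.342). Fibroblast markers gave 5 higher and 2 lower of 11 in HCC1395 (median 0.16, camera adjusted p = 0.0407, adjusted p = 0.084 with an estimated correlation), where COL1A1 stood at 59.7 CPM in DMSO and 47.4 CPM under both. Under EZH2i alone they gave 4 higher and 2 lower (4 and 3 adjusted over the list alone, median 0.35, camera adjusted p = 0.0349, adjusted p = 0.0931 with an estimated correlation) and in the combination against AKTi 3 and 2 (3 and 4, median 0.11, camera adjusted p = 0.0175, adjusted p = 0.088 with an estimated correlation). Median and mean differed in sign in HCC38, with 3 higher and 1 lower of 7 (3 and 2 adjusted over the list alone, median -0.01, mean 0.21, upward test, camera adjusted p = 0.655), and in HCC1937, with 5 and 5 of 11 (median -0.33, mean 1.18, upward test, camera adjusted p = 0.915). Endothelial and myeloid markers gave 1 higher and 0 lower of 9 in HCC1395 (median 0.36, camera adjusted p = 0.743) and 6 higher and 1 lower of 11 in HCC1937 (median 0.51, 0.166), and only 3 were measured in HCC38. Adjusted over the list alone the other counts were the same, except 6 and 2 for endothelial and myeloid markers in HCC1937.

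The share of counts from replication-dependent histone genes, which lack a poly(A) tail in cycling cells, was 0.301% in HCC38 DMSO and 0.240% under both. It was 0.072% and 0.119% in HCC1937 and 0.022% and 0.028% in HCC1395.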
